A study of Mus musculus with 18 samples.

How the data were processed

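Total RNA came from cultured mouse cortical neurons of postnatal day 0 animals after 7 days in vitro and 0, 1 or 6 h of KCl, per the labels' protocols. The same labels also call the cultures embryonic, and postnatal day 0 was taken. RNA was purified on RNeasy columns, 200 ng of total RNA was labelled by in vitro transcription with biotin, and the cRNA was hybridised to mouse Affymetrix arrays of sets A and B, also per the labels' protocols. The labels name 9 arrays of each set, 3 per time, numbered 1 to 3 within each time. The series text describes 3 independent experiments. The KCl concentration is 55 mM in the sample labels and 50 mM in the series text.

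The deposited values are linear intensities, with 1 summary value per probe set and array. Scanner software, background correction and summary method are not given in the sources used here. From the values themselves, each array had been scaled by the authors to a 2% trimmed mean near 500. On set B the 3 arrays numbered 1 hold values below 0 (27.6%, 27.4% and 28.0% of probe sets at 0, 1 and 6 h), while the other 6 arrays and all arrays of set A hold none. The set B table was thus made with more than 1 summary method, and that difference coincides with replicate number 1. Run files were present for the 9 set B arrays only and named 1 chip lot and 1 scan day.

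All computations started from these values. Values below 0 were set to 0, 16 was added, and log2 was taken. Where array medians of a set lay within 0.5 log2 of each other the deposited scale was kept, and otherwise the arrays were quantile-normalized. The spread of medians was 0.24 log2 on set A, which kept its scale, and 0.56 on set B, which was quantile-normalized. Signals are quoted on the deposited scale. The 64 control probe sets of each array and the 25% of probe sets with the lowest mean were left out of the tests. This left 16969 of 22626 probe sets on set A and 16883 of 22511 on set B. Probe sets that carry 1 gene symbol numbered 20380 on set A and 14661 on set B; 691 and 245 carry several and were not named, and 1555 and 7605 are unnamed here. Of the tested ones, 15565 and 11607 carry 1 symbol. Over 100 probe sets present on both sets, set B values were 4.13 times those of set A at the median, so levels were not compared between sets. Positions of the genes were taken from the GRCm38.p6 annotation for the order of neighbouring genes alone.

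Each array set was fitted separately with limma 3.58.1 in R 4.3.3 (lmFit on a means model of the 3 times over 9 arrays, eBayes with an intensity trend). The contrasts were 1 h against 0 h, 6 h against 0 h and 6 h against 1 h. The p-values were two-sided and adjusted by Benjamini-Hochberg within array set and contrast, and an adjusted p under 0.05 counted as changed. Tables were handled with the data.table package, version 1.17.8, robust fits drew on statmod 1.5.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The number of arrays limits the precision of all estimates.

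Each gene was represented by its probe set of highest mean, on set A where it had a tested one and otherwise on set B, leaving out cross-hybridising (_x_at) probe sets unless no other existed. This gave 15232 genes, 9981 of them on set A. The genes named in the text follow a rule. For each contrast against 0 h it takes the 10 largest rises and the 10 largest falls past the threshold with all 3 same-numbered differences of that sign, and for 6 h against 1 h the 5 largest of each. For each gene list it takes up to 4 members past the threshold and up to 2 that did not pass. Fos, Npas4, Arc, Bdnf, Gad1 and Gad2 are always given. Some further list members are named as examples of their list after their values were seen.

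The 22 gene lists were written from general knowledge of neuronal biology. They hold 548 entries and 543 distinct symbols, of which 5 stand in 2 lists. Of these, 475 were measured and 68 were not among the named probe sets tested. They cover immediate early transcription factors, neuropeptides and secreted factors, signalling effectors, negative regulators of MAP kinase and related signalling, inhibitory synapse, interneuron identity, excitatory synapse, presynaptic vesicle, voltage-gated channel and neuronal structural genes. They also cover cholesterol synthesis, glycolysis and glucose uptake, respiratory chain, unfolded protein response, heat shock, circadian clock, ribosomal protein and cell cycle genes, and markers of astrocytes, oligodendrocyte lineage, microglia, and vascular cells and fibroblasts. A list counted as shifted when camera in limma, with a preset correlation of 0.01 and 1 probe set per gene on set A, gave an adjusted p under 0.05 over the 22 lists. Members measured only on set B were counted per gene. The same test with a correlation estimated per list, and fry, were run beside it.

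Whether replicate numbers mark shared experiments was checked by correlating, between arrays of the same number, the deviations from the mean of their time. On set B all 9 such correlations were above 0.1 (0.150 to 0.476). In 7 of 9 comparisons of an array with those of a later time, the best match was its own number. Differences between replicates 2 and 3, neither of which holds values below 0, had correlations from -0.00258 to 0.0218 between times on set B. The same-number correlation there thus goes with the apparent summary method. On set A only 2 of 9 were above 0.1 (0.0181 to 0.174), which is short of the rule that every correlation exceed 0.1, so numbers were not treated as pairs. The best match on set A was nevertheless the own number in 9 of 9 comparisons, and pairs of unlike number ran from -0.137 to 0.0343. Whether numbers mark shared experiments therefore remains open. The main design was kept without a block in both sets, and set B counts with a block are given beside the main ones. Set A counts with a block are given in the section on how the results depend on the processing.

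A 5' to 3' ratio was taken per array from the Actb and Gapdh control probe sets. Probe sets of bacterial transcripts that are not added to the sample (27 per set) gave the background level as their 95th percentile. To set the overlap of the 1 h and 6 h changes beside chance, unchanged groups were simulated 100 times against shared controls.

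The steps were tested on simulated data drawn from the real means and spreads. Errors were drawn independently for each array and probe set. The simulation thus held no 5' to 3' difference between times, replicate effect or correlation between genes, and the rates below do not cover these. On set A the share of simulated changes of 2, 1, -1 and -2 log2 units that was recovered was 100%, 60.0%, 45.7% and 92.9% for 1 h against 0 h. The shares were 98.0%, 58.0%, 43.8% and 94.9% for 6 h against 0 h, and 100%, 62.0%, 46.8% and 95.3% for 6 h against 1 h. On set B they were 46.0%, 10.2%, 13.3% and 29.3%, then 42.0%, 14.0%, 15.2% and 15.9%, then 36.7%, 6.12%, 8.89% and 30.2%. False calls made up 4.11%, 5.56% and 5.26% of the calls on set A and 6.12%, 2.33% and 7.32% on set B, in the same order. A shift put into 1 of 22 lists over 9981 genes was found with 0 others called. Time classes were simulated with 40 genes each and changes larger than 2 log2 units. Each class then held 40 genes, which were not matched to the simulated ones, and smaller changes were not tried.

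Groups, contrasts, tests, lists, the rule for named genes and most alternatives were set before the data were examined. The alternatives covered the pseudocount (1 or 64), scaling, filter, eBayes options, array weights, fits of 6 arrays, a replicate block, leaving out each array, and the probe set choice. The summary-method block, the fits of replicates 2 and 3, the fit with the log2 Gapdh 5' to 3' ratio as a covariate and the fit of the brightest probe sets were added after the values had been seen. Probe-level data were not used here.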

Results

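Gene expression was measured in cultured mouse cortical neurons prepared on postnatal day 0 per the labels (which also call the cultures embryonic) and kept for 7 days in vitro. The cultures were exposed to a raised concentration of potassium chloride (KCl) for 0, 1 or 6 h. A raised potassium concentration depolarizes the neuronal membrane, and the stated aim was to open L-type voltage-sensitive calcium channels at a stage when inhibitory synapses were forming. The sample labels give the concentration as 55 mM and the series text gives 50 mM. Labelled cRNA was hybridised to a pair of Affymetrix array types that carry different probe sets, called array sets A and B here. Each time had 3 arrays per set, from 3 independent experiments per the series text, so each set held 9 arrays and n = 3 per time throughout. The 0 h cultures were the untreated controls. The labels name no untreated cultures at 1 h or 6 h, so effects of time and handling cannot be told apart from those of KCl.

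The deposited signals were linear intensities, scaled so that every array had nearly the same trimmed mean. Array medians ran from 163 to 196 on set A and from 182 to 275 on set B. The 95th percentile of bacterial control probe sets that no added transcript should light up was 74.8 units on set A and 369 units on set B. Signals below these levels lay within the range of the background, and a fold with such a signal on 1 side is limited by it in size and rank. After the dimmest probe sets were left out, 16969 probe sets of set A and 16883 of set B were tested. The median residual SD was 0.28 log2 units on set A and 0.78 on set B. The number of arrays limits the precision of every value below. All fold changes are on the log2(value + 16) scale, which understates the change of dim genes. Each is given with its standard error (SE), and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

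A sign of RNA or cRNA quality moved with time. The ratio of 5' to 3' signal of the Actb control probe sets on set A was 0.391 ± 0.122 (SD, n = 3) at 0 h, 0.669 ± 0.0496 at 1 h and 0.574 ± 0.0204 at 6 h. The same ratio of Gapdh was 0.859 ± 0.195, 1.17 ± 0.103 and 1.21 ± 0.0427. A two-sided exact permutation test of Actb gave p = 0.1 for 1 h and for 6 h against 0 h, which is the smallest p that 3 arrays against 3 allow. For Gapdh the exact p was 0.2 at 1 h and 0.1 at 6 h. Every comparison with the 0 h arrays below carries this difference.

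**Figure D1:**
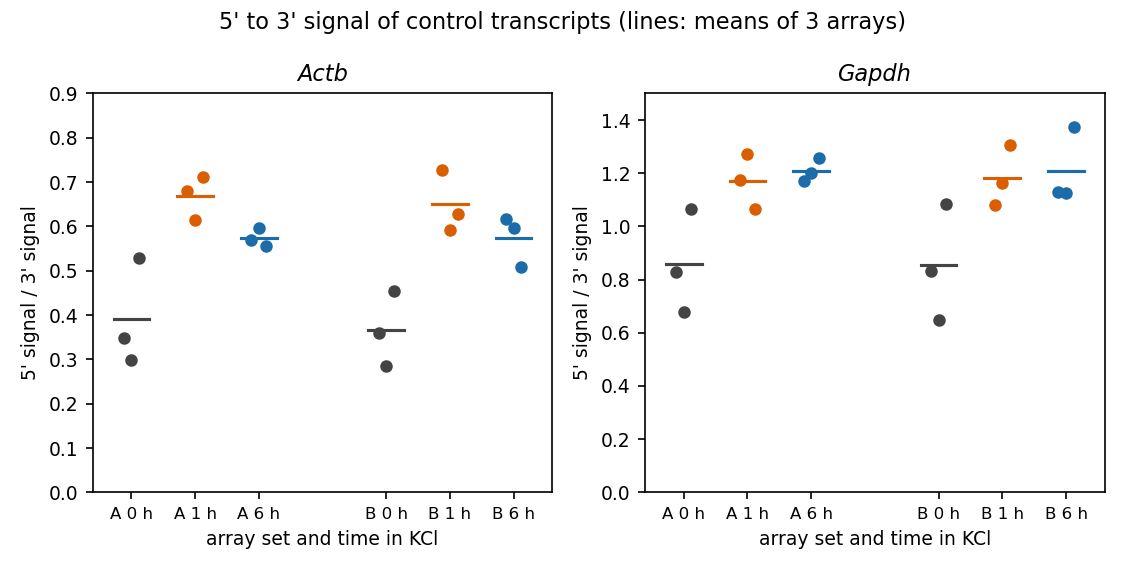
Ratio of 5' to 3' signal (no unit) of the Actb and Gapdh control probe sets on each array, by array set and time in KCl; points are single arrays and lines are means of 3. On set A the Actb mean was 0.391 at 0 h, 0.669 at 1 h and 0.574 at 6 h, and the Gapdh mean was 0.859, 1.17 and 1.21.

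The first comparison asked which transcripts differed after 1 h of KCl. The largest rises belonged to immediate early genes, which are transcribed without new protein synthesis. Fos, a subunit of the AP-1 transcription factor, went from a mean signal of 245 ± 61.8 (SD, n = 3) to 24849 ± 5054. This was a 95.9-fold rise (log2 6.58 ± 0.19 SE, adjusted p = 1.73e-10). The zinc-finger factor Egr1 rose 53.5-fold, from 555 ± 85.0 to 30485 ± 3663 (log2 5.74 ± 0.14, adjusted p = 9.33e-11). Arc, which takes part in the endocytosis of AMPA receptors at synapses, rose from 27.3 ± 3.46 to 1668 ± 677 (log2 5.21 ± 0.31, adjusted p = 4.61e-07). Npas4, an activity-dependent transcription factor carried by set B, reached 32423 ± 8084 at 1 h (log2 9.16 ± 0.41, adjusted p = 4.14e-07). Its 0 h signal of -131 ± 381 lay within the background, so the size of this fold depends on the added 16 units. Arc, Junb, Fosb and Egr4 also had 0 h means at or below the set A background level.

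The remaining top rises were Junb (log2 6.37), Fosb (5.74), the orphan nuclear receptor Nr4a1 (5.58), Ier2 (4.99), Egr2 (4.68) and Egr4 (4.60). Among the falls, Txnip, an inhibitor of thioredoxin and of glucose uptake, fell by 2.54 ± 0.43 on the log2 scale, from 1346 ± 208 to 225 ± 79.8 (adjusted p = 0.00622). The Notch target Hes5 (log2 -2.37 ± 0.45), Zfp235 (-2.35), Cdc42ep5 (-1.83), the hyaluronidase gene Hyal2 (-1.80), Zfp329 (-1.74) and Zfp30 (-1.72) also fell. So did Ms4a7 (-1.54), Dnaja3 (-1.51) and Ppp1r3c (-1.34 ± 0.16), which targets a phosphatase to glycogen. The 1 h means of Hes5, Zfp235, Cdc42ep5, Zfp329, Zfp30 and Ms4a7 lay within the background, so the sizes and ranks of their falls are limited by it. Of the other probe sets, that of Dnaja3 stood at -0.10 and that of Ppp1r3c at 0.10, and neither passed. Those of Txnip (-1.49), Hes5 (-0.86) and Zfp329 (-0.75) pointed downward without passing.

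**Figure D2:**
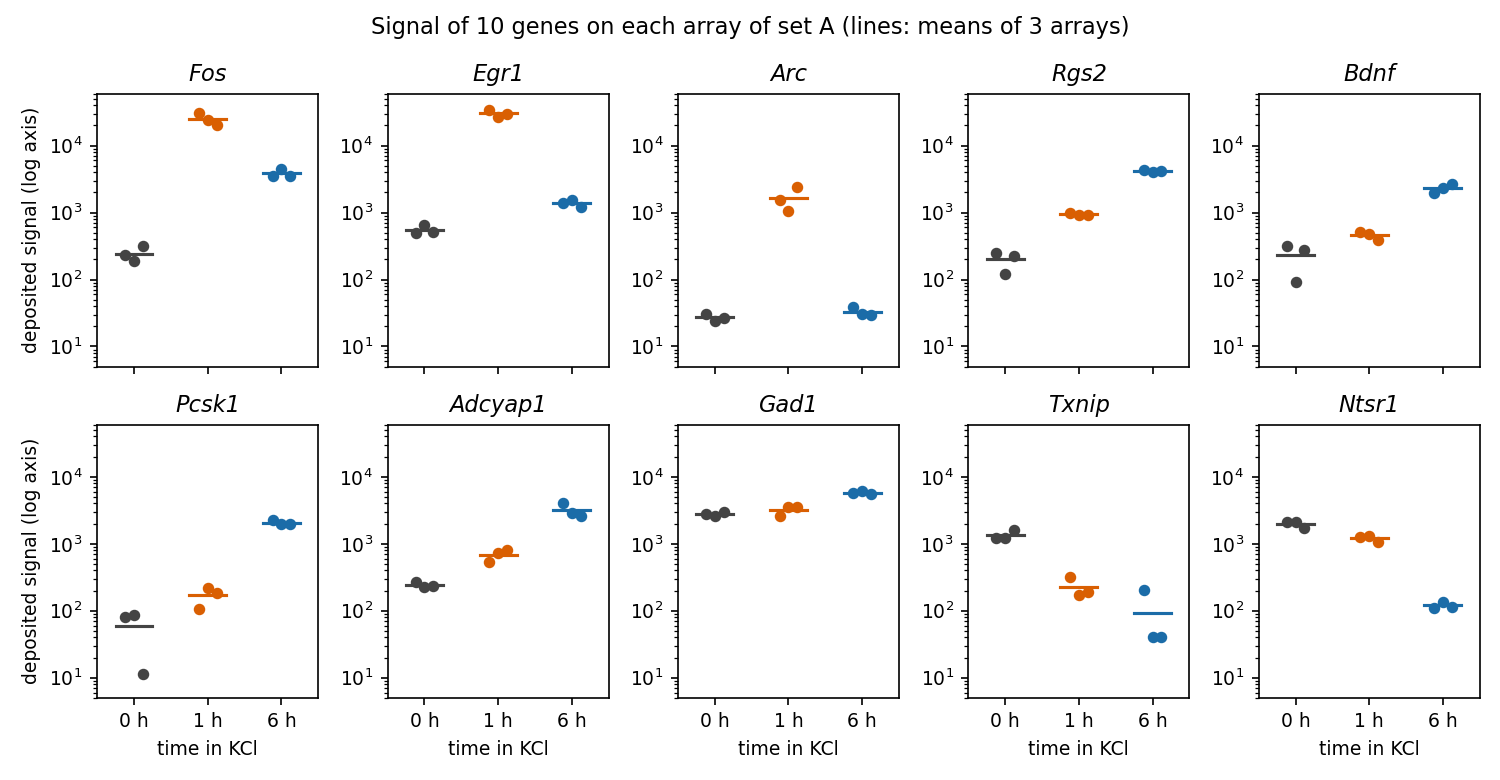
Deposited signal (log axis, arbitrary units) of 10 genes on each of the 9 arrays of set A at 0, 1 and 6 h of KCl; points are single arrays and lines are means of 3. Fos averaged 245, 24849 and 3862 units, Arc 27.3, 1668 and 33.3, Bdnf 229, 458 and 2308, and Ntsr1 1966, 1205 and 120.

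Of 32 measured immediate early transcription factors and related early genes, 22 rose at 1 h, 1 fell and 9 did not pass. The one that fell was the repressor Klf10 (log2 -0.96 ± 0.25, adjusted p = 0.0474). The list was shifted upward against the other genes of set A (camera adjusted p = 1.55e-36, and adjusted p = 0.00133 with an estimated correlation). Among 24 activity-regulated effectors of synaptic and cell signalling, 11 rose and 1 fell (camera adjusted p = 9.90e-18, and adjusted p = 0.0299 with an estimated correlation). Besides Arc, the rises included Gadd45b (log2 3.50 ± 0.30), a stress-inducible gene, and the G-protein regulators Rgs2 (2.23 ± 0.20) and Rgs4 (2.22 ± 0.12). This list and the immediate early list are defined by response to activity, so their upward shift follows in part from how members were chosen. Of 21 negative regulators of MAP kinase and related signalling, 5 rose and none fell (camera adjusted p = 8.53e-08, and adjusted p = 0.0299 with an estimated correlation). The phosphatase genes Dusp1 (log2 4.49 ± 0.14) and Dusp6 (3.61 ± 0.22) led them, and Siah2, Errfi1 and Dusp4 rose by 1.44, 1.16 and 0.93. In the circadian clock list 2 of 20 genes rose, Nfil3 (2.79 ± 0.21) and Per1 (1.10 ± 0.15), and the list shifted upward (camera adjusted p = 5.23e-04, and adjusted p = 0.0299 with an estimated correlation). Nfil3 is also a member of the immediate early list. The number of lists called with the preset correlation does not by itself set the real grouping apart. As many were called in 5 of 10 splits of the 1 h and 0 h arrays, the real one included.

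The other 18 lists did not pass at 1 h (camera adjusted p from 0.0568 to 0.862). The lowest value, 0.0568, belonged to ribosomal protein, respiratory chain and astrocyte genes, all downward. By fry, a test of each list by itself, astrocyte genes were lower (adjusted p = 0.00712) and heat shock genes higher (adjusted p = 0.0240). In 6 of them (presynaptic, cholesterol, unfolded protein, cell cycle, microglial and vascular genes) the median, the mean and the test on set A did not all point the same way. Of 26 neuropeptides and other secreted factors, 4 rose: Vgf (2.15), Scg2 (1.59), Adcyap1 (1.41) and Pnoc (0.76). In the unfolded protein response list 3 of 22 genes rose, with Atf4 (1.29 ± 0.14) first, and Calr fell by 0.56. The heat shock cochaperone gene Dnajb1 rose (1.94 ± 0.15), the only one of its 14 list members to pass on the brightest probe set. Of the 3 set A probe sets of Hsp90aa1, 2 rose (up to 1.05). Mapt (0.77) and Nefl (0.84) rose among 18 neuronal structural genes, and Cyp51 (0.52) among 19 cholesterol synthesis genes. The presynaptic vesicle list had 1 rise, Syt1 (1.81 ± 0.36), and 1 fall, Syp (-0.82 ± 0.13), among 22 genes. A single member fell on its brightest probe set in each of the inhibitory synapse list (Slc6a11, -1.06), the excitatory synapse list (Dlg3, -0.69) and the astrocyte list (Slc1a3, -0.54). Of the probe sets of Gfap 1 of 2 also fell, as did 1 of 4 of Clu. Other probe sets of Slc1a3 (up to 1.11) and Cyp51 (down to -0.08) pointed the other way without passing. The other probe set of Syp stood at -0.14 and did not pass. On the brightest probe sets no member passed in the lists of interneuron identity, voltage-gated channels, glycolysis, respiratory chain, ribosomal proteins, cell cycle, oligodendrocyte lineage, microglia, or vascular and fibroblast markers. Among these lists, another probe set of Satb1 rose (0.95), 1 of Sparc rose (0.78) and 1 of Cox5a fell. Bdnf stood at log2 1.10 ± 0.33 (adjusted p = 0.0785) on its brightest probe set, and another of its probe sets passed at 1.97. Gad1, which encodes a GABA-synthesizing enzyme, stood at 0.19 ± 0.13 (adjusted p = 0.486) on its brightest probe set, while its other probe set passed at 1.21. Gad2 stood at 0.34 ± 0.23 (adjusted p = 0.448).

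In total, 707 probe sets of set A changed at 1 h, 552 upward and 155 downward. On set B 37 changed, 30 upward and 7 downward. Set B gave 14 upward and 1 downward on the deposited scale, and 5 upward and none downward after median scaling. Its count was 5 with eBayes without trend, 4 with the Gapdh 5' to 3' ratio as a covariate, and from 9 to 70 when 1 array was left out (9 without the 1 h replicate 3, 70 without the 0 h replicate 3). Taking the brightest probe set of each gene, 167 of 15232 named genes rose and 105 fell. Across the lists, 58 of 475 measured members changed at 1 h (51 upward) on the brightest probe set. The number was 77 on the probe set with the smallest p, and 81 when adjusted over the list alone. With the summary method of the set B arrays as a block, 111 of its probe sets changed, and 116 with the replicate number as a block. The set A count was 64 (63 upward) with the Gapdh 5' to 3' ratio as a covariate, a fit in which Fos, Egr1, Junb, Nr4a1 and Arc passed and none of the 10 largest falls did. Leaving out the 0 h replicates 1, 2 and 3 in turn gave 293, 316 and 1308 on set A, and leaving out the 1 h replicates 1 and 3 gave 353 and 277.

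The second comparison asked which transcripts differed after 6 h. Genes of secreted peptides and their processing were now among the largest rises. Pcsk1, a protease that cleaves prohormones, went from 59.5 ± 41.9 (SD, n = 3) to 2067 ± 148, with its 0 h mean below the background level (log2 5.01 ± 0.42 SE, adjusted p = 9.62e-06). Adcyap1, which encodes the neuropeptide PACAP, rose 12.1-fold, from 243 ± 22.7 to 3176 ± 776 (log2 3.60 ± 0.19, adjusted p = 1.94e-07). Bdnf, a neurotrophin, rose 10.5-fold, from 229 ± 120 to 2308 ± 325 (log2 3.39 ± 0.33, adjusted p = 2.41e-05). Rgs2 rose 20.2-fold, from 199 ± 68.6 to 4173 ± 129 (log2 4.34 ± 0.20, adjusted p = 4.41e-08). Fos was still 15.0-fold above 0 h (log2 3.91 ± 0.19, adjusted p = 4.80e-08).

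The other top rises were Npas4 (log2 7.65) and Chst8 (4.07), both from set B with 0 h signals within the background, and Nfil3 (3.46), Nr4a1 (3.45) and Rgs4 (3.42). Among the falls, the neurotensin receptor gene Ntsr1 went from 1966 ± 237 to 120 ± 14.2 (log2 -3.86 ± 0.15, adjusted p = 8.71e-09). Txnip fell by 3.94 ± 0.43 (adjusted p = 6.14e-05). Its 6 h signals were 201, 40.1 and 40.5 units on replicates 1, 2 and 3, the last 2 of them within the set A background, which limits the size of this fall. The remaining 8 of the 10 largest falls were measured on set B. They were Trim45 (-4.42 ± 0.53), the ubiquitin ligase gene Lrsam1 (-3.93 ± 0.44), Galnt9 (-3.91), Ccbe1 (-3.75), Pcnx2 (-3.74), Dnajb14 (-3.46), Phyhip (-3.11) and Nceh1 (-2.98). All of these 8 had 6 h means within the set B background, so their sizes and ranks are limited by it. Only 1 of 4 probe sets of Ccbe1 and 1 of 3 of Nceh1 fell, and the highest stood at 0.19 and 0.04.

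Of 32 immediate early genes, 18 rose against 0 h, 2 fell and 12 did not pass (camera adjusted p = 2.79e-11, and adjusted p = 0.0360 with an estimated correlation). Crem, a cAMP-responsive factor, stood at 2.63 ± 0.17 and Maff, with a 0 h mean within the background, at 3.25 ± 0.25, while Klf10 (-1.41) and Myc (-0.86) fell. Of 26 neuropeptides and secreted factors, 11 rose and 1 fell (camera adjusted p = 1.75e-09, and adjusted p = 0.0485 with an estimated correlation). Scg2, a granule protein of secretory vesicles, rose from 1730 ± 56.7 to 16386 ± 388 (log2 3.23 ± 0.10). Vgf (2.75), Nptx2 (2.56), Pnoc (2.30), Nrn1 (1.60), Tac1 (1.59), Nts (1.43) and Plat (0.60) also rose. Grp, which encodes gastrin-releasing peptide, fell by 2.28 ± 0.40 (adjusted p = 0.00145), to a mean within the background.

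Of 24 signalling effectors, 16 rose and 1 fell (camera adjusted p = 2.79e-11, adjusted p = 0.0747 with an estimated correlation). Sgk1 (2.38 ± 0.21), the scaffold gene Homer1 (2.09 ± 0.24) and Syt4 (1.59 ± 0.11) were among them, and Cdk5r1 fell by 1.23. Arc stood at 0.18 ± 0.31 (adjusted p = 0.734). Of 21 negative regulators of MAP kinase and related signalling, 11 rose and 1 fell (camera adjusted p = 3.55e-06, adjusted p = 0.0732 with an estimated correlation). They included Dusp1 (3.06), Dusp4 (2.53), Dusp6 (2.44) and Errfi1 (1.68), while Dusp2 fell by 1.00.

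Genes of cholesterol synthesis rose at 6 h in 8 of 19 cases and fell in 2 (camera adjusted p = 0.00259, adjusted p = 0.131 with an estimated correlation). Sc5d (1.93 ± 0.21), Cyp51 (1.68 ± 0.10), Msmo1 (1.47 ± 0.14) and Idi1 (1.32 ± 0.16) rose, and Dhcr7 (-1.28 ± 0.17) and Mvk (-1.01 ± 0.23), which act in the same pathway, fell. In the circadian list 6 of 20 genes rose and 1 fell (camera adjusted p = 0.0479, adjusted p = 0.131 with an estimated correlation). Its test and mean on set A (0.38) pointed upward while its median there was -0.05. Nfil3, Rorb (1.46), Cry2 (1.30) and Per1 (1.19) led it. The preset test called as many lists in 5 of 10 splits of the 6 h and 0 h arrays, the real one included.

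The lists of synaptic and neuronal genes did not pass as sets by camera, and members moved both ways. The camera adjusted p of the 16 lists that did not pass at 6 h ran from 0.112 to 0.958. Median, mean and test on set A differed in sign for the voltage-gated channel, neuronal structural, heat shock, microglial and vascular lists. In the excitatory synapse list 9 of 31 genes fell and 1 rose (camera adjusted p = 0.457, and adjusted p = 0.00220 downward by fry). Cacng2, an auxiliary subunit of AMPA receptors, fell to a 6 h mean within the background (log2 -2.65 ± 0.56), and its set B probe sets stood at -0.93 and -0.88. Lower as well were the kainate receptor gene Grik5 (-1.49 ± 0.20) and the AMPA receptor gene Gria1 (-0.87 ± 0.12), while Dlg1 rose (0.84 ± 0.15). In the inhibitory synapse list 4 of 23 genes fell and 1 rose (adjusted p = 0.431 with an estimated correlation). The gene that rose was Gad1, from 2776 ± 213 to 5804 ± 243 (log2 1.06 ± 0.13, adjusted p = 1.53e-04), and both of its probe sets passed. Nlgn3 (-1.26), the GABA transporter Slc6a11 (-1.17), the chloride transporter Slc12a5 (-1.01) and Abat (-0.57), which breaks down GABA, fell. The other probe sets of Slc12a5 (0.34) and Abat (-0.02) did not pass. Gad2 stood at 0.49 ± 0.23 (adjusted p = 0.143). Of 15 interneuron identity genes 4 fell and 1 rose (camera adjusted p = 0.958), with Lhx6 at -1.43 ± 0.25 and Satb1 at 0.82 ± 0.18. The other probe set of Lhx6 stood at -0.01, and 2 of 3 probe sets of Satb1 rose. In the presynaptic vesicle list 4 of 22 fell and 2 rose (camera adjusted p = 0.952), among them Syp (-0.79), Syt1 (1.68) and Snap25 (0.72). Of 34 voltage-gated channel genes 5 fell and 3 rose (camera adjusted p = 0.937), with Cacna1b at -1.28 and Kcnj3 at 1.10. In the neuronal structural list 3 of 18 rose and 2 fell (camera adjusted p = 0.597). The neurofilament genes Nefl (2.45 ± 0.21) and Nefm (1.34 ± 0.20) rose, and Ncam1 (-0.89) and Tubb3 (-0.83) fell. Only 1 of 2 set A probe sets of Syp and of Gria1 fell, and the others stood at -0.17 and -0.21. Of the 3 probe sets of Ncam1 1 fell, and the highest stood at -0.27.

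Among metabolic and stress lists, 6 of 19 glycolysis and glucose uptake genes rose and 3 fell (camera adjusted p = 0.195), with the glucose transporter genes Slc2a1 (0.98 ± 0.23) and Slc2a3 (0.95 ± 0.11) up and Aldoc (-1.02 ± 0.11) down. Only 1 of 3 probe sets of Slc2a1 rose, and the lowest stood at 0.14. In the unfolded protein response list 6 of 22 rose and 2 fell (adjusted p = 0.798 with an estimated correlation), led by Herpud1 (1.41) and Chac1 (1.38). In the heat shock list 1 of 14 rose (Hspa4l, 0.89) and 2 fell (camera adjusted p = 0.958). Of these, Dnaja1 stood at -0.35 on its brightest probe set and at 0.46 on its other one, and both passed. Other probe sets of Hsp90aa1 (2 of 3 on set A, up to 1.01), Dnajb1 (0.96) and Hsph1 (0.68) rose. Ribosomal protein genes had 3 rises and 1 fall among 22 (camera adjusted p = 0.112), and respiratory chain genes had 1 rise among 31 (Atp5b, 0.46, adjusted p = 0.948 with an estimated correlation). Cell cycle genes had 3 falls among 22 (camera adjusted p = 0.597). Of the markers of other cell types, 5 of 17 astrocyte genes fell and 1 rose (camera adjusted p = 0.407, and adjusted p = 0.00445 downward by fry), with Gfap at -0.70 ± 0.23 and Vim at 0.82 ± 0.16. Cspg5 (-0.76) was the only one of 16 oligodendrocyte lineage genes to pass (camera adjusted p = 0.958). Cd68 (0.92) was the only one of 14 microglial genes to pass (camera adjusted p = 0.952), and Pecam1 (-1.54, with a 6 h mean within the background) the only one of 18 vascular and fibroblast genes (camera adjusted p = 0.958).

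**Figure D3:**
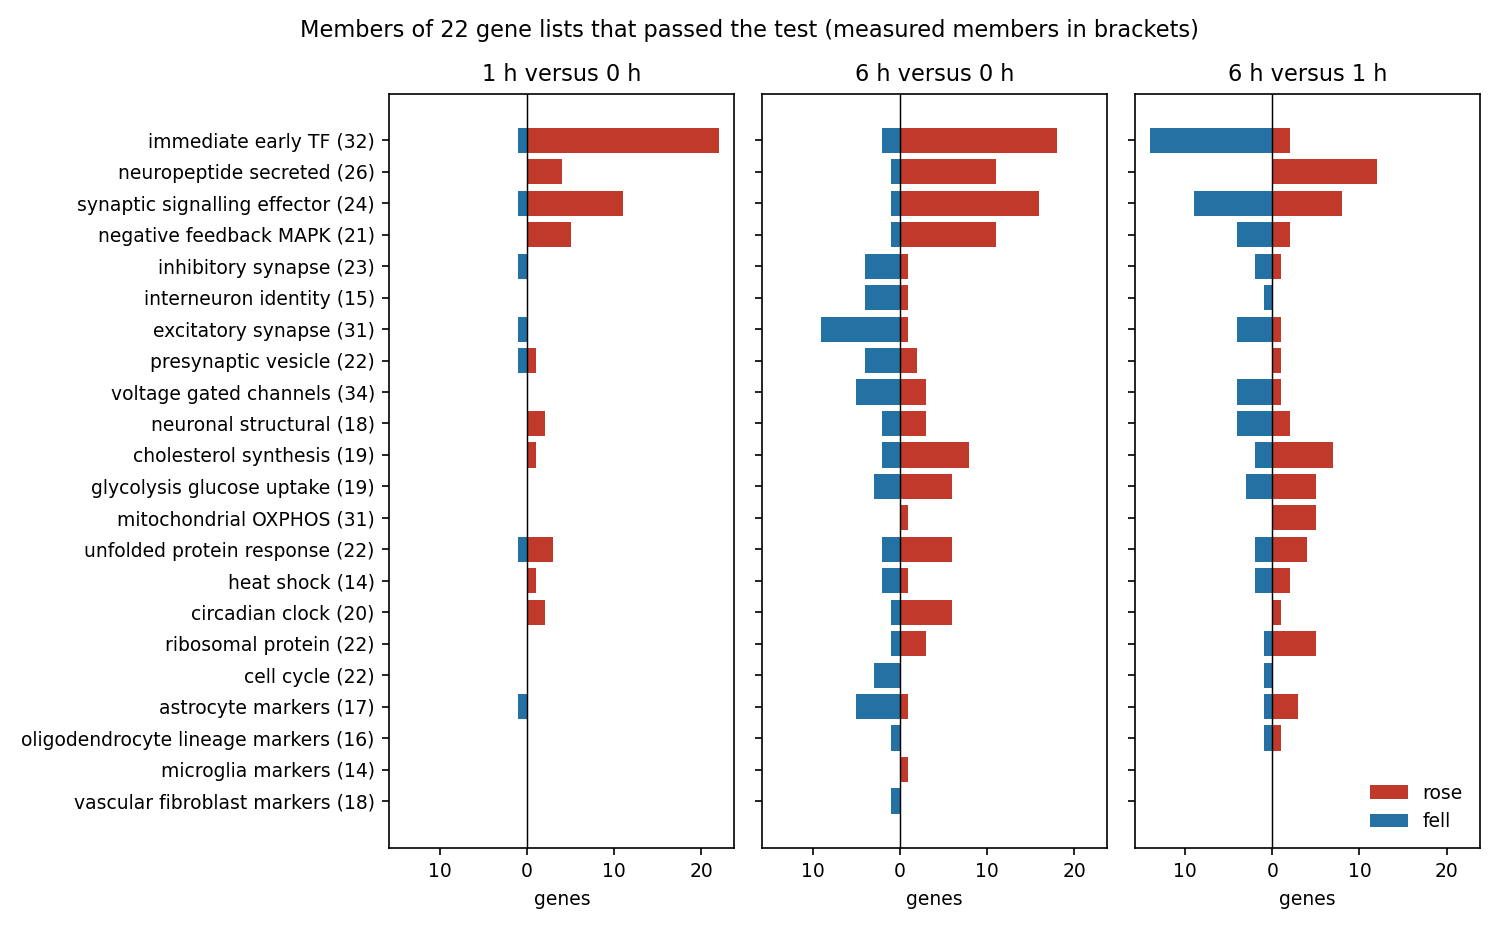
Number of genes (horizontal axis) in each of 22 gene lists that rose (right of 0) or fell (left of 0) in each comparison at an adjusted p under 0.05, with the number of measured members in brackets. Of 32 immediate early genes 22 rose at 1 h and 18 at 6 h against 0 h, and 14 fell between 1 h and 6 h; of 26 neuropeptide and secreted factor genes 4 rose at 1 h and 11 at 6 h.

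At 6 h 3753 probe sets of set A changed, 1772 upward and 1981 downward, and 846 of set B changed, 376 upward and 470 downward. The excess of falls was not stable. On set A 829 rose and 552 fell among changes of at least 2-fold, 1851 rose and 1738 fell with median scaling, and rises exceeded falls without the 0 h replicate 1 (1411 and 1383) or 3 (1970 and 1766). On set B rises exceeded falls with eBayes without trend (89 and 61) and without the 0 h replicate 2 (233 and 196) or 3 (328 and 289). The set B count was 443 on the deposited scale, 127 with median scaling and 150 with eBayes without trend. On the brightest probe set of each gene, 931 named genes rose and 1602 fell. Across the lists, 152 of 475 measured members changed (99 upward), 197 did on the probe set with the smallest p, and 165 did when adjusted over the list alone. With the summary method as a block, 1428 probe sets of set B changed, and 1468 with the replicate number as a block. The set A count was 584 (335 upward, 249 downward) with the Gapdh 5' to 3' ratio as a covariate, a fit in which Pcsk1, Rgs2, Adcyap1, Bdnf, Ntsr1, Txnip and Gad1 passed. The set B count was 551 and 429 without the 0 h replicates 1 and 2.

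The third comparison set 6 h against 1 h, and the 0 h arrays still entered it through the shared estimate of the spread, the filter, the choice of probe set and the scaling of set B. Its largest falls included immediate early genes and its largest rises included genes of secreted factors. Arc fell by 5.02 ± 0.31 (SE, n = 3 per time) on the log2 scale, from 1668 ± 677 to 33.3 ± 5.06 (adjusted p = 1.28e-06). Egr1 fell by 4.43 ± 0.14, from 30485 ± 3663 to 1395 ± 162 (adjusted p = 3.10e-09), and Ier2 stood lower as well (log2 -3.99 ± 0.17, adjusted p = 2.48e-08). Pcsk1 rose by 3.53 ± 0.42 (adjusted p = 2.21e-04), and Nptx2, a pentraxin that clusters AMPA receptors, rose 7.00-fold (log2 2.81 ± 0.32, adjusted p = 1.45e-04). The other probe set of Nptx2 stood at 0.63 without passing. Fam126b rose by 2.64 ± 0.21 (adjusted p = 9.08e-06), while none of its 3 set B probe sets passed (0.20 to 1.43). On set B, Chst8 (4.15 ± 0.75) and 4930556A17Rik (3.31 ± 0.75) rose, and Trim45 (-4.14 ± 0.53) and Lrsam1 (-4.05 ± 0.44) fell. The lower side of each of these 4 changes, and of that of Arc, lay within the background, which limits their sizes and ranks. Npas4 stood at -1.52 ± 0.41 (adjusted p = 0.0864).

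Of 32 immediate early genes, 14 fell between 1 h and 6 h and 2 rose, Crem (1.70 ± 0.17) and Fosl2 (0.84 ± 0.23). The list shifted downward (camera adjusted p = 8.73e-07, adjusted p = 0.0676 with an estimated correlation). Of 26 neuropeptides and secreted factors 12 rose and none fell (camera adjusted p = 9.86e-10, adjusted p = 0.0676 with an estimated correlation). Besides Pcsk1 and Nptx2, they included Bdnf (2.29 ± 0.33), Adcyap1 (2.19 ± 0.19) and Cck (0.68 ± 0.16). Of 19 cholesterol synthesis genes 7 rose and 2 fell (camera adjusted p = 0.00111, adjusted p = 0.176 with an estimated correlation). Of 31 respiratory chain genes 5 rose, such as Uqcrh (0.68 ± 0.19), and of 22 ribosomal protein genes 5 rose, such as Rps19 (0.68 ± 0.15), while Rpl22 fell (-0.68 ± 0.14) and its other probe set stood at 0.42. These last lists shifted upward by the preset test (camera adjusted p = 0.00111 and 7.17e-04). The adjusted p with an estimated correlation was 0.782 for the respiratory chain and 0.619 for the ribosomal proteins, and by fry it was 0.205 and 0.0949. As many lists were called by the preset test in 2 of 10 splits of the 6 h and 1 h arrays, the real one included.

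Signalling effectors moved both ways, with 8 rises and 9 falls among 24 (camera adjusted p = 0.604). Rgs2 (2.11), Sgk1 (1.75) and Homer1 (1.34) rose, while Arc, Gadd45b (-2.58) and Mcl1 (-1.28) fell. The test and median of this list (0.21) pointed upward and its mean was -0.06. Among the negative regulators of MAP kinase and related signalling 2 rose and 4 fell, with Dusp4 at 1.61 and Dusp1 at -1.42 (camera adjusted p = 0.730). Gad1 rose by 0.88 ± 0.13 (adjusted p = 0.00118), and Abat and Slc12a5 fell in the same inhibitory synapse list (camera adjusted p = 0.730). The other probe set of Abat stood at 0.17 and did not pass. Excitatory synapse genes had 4 falls and 1 rise (camera adjusted p = 0.138, and adjusted p = 0.00502 downward by fry), and voltage-gated channel genes likewise had 4 falls and 1 rise (camera adjusted p = 0.730). Glycolysis genes had 5 rises and 3 falls (camera adjusted p = 0.0578, and adjusted p = 0.00813 upward by fry). The unfolded protein response list had 4 rises and 2 falls (camera adjusted p = 0.185). Dnajb1 fell by 2.39 ± 0.15 among 2 falls and 2 rises of the heat shock list (camera adjusted p = 0.730, and adjusted p = 0.00801 downward by fry). Neuronal structural genes had 2 rises and 4 falls (camera adjusted p = 0.768). Astrocyte genes had 3 rises and 1 fall (camera adjusted p = 0.730). The other lists had at most 1 member up and 1 down (camera adjusted p from 0.604 to 0.943). Median, mean and test on set A also differed in sign for the MAP kinase, inhibitory synapse, circadian, astrocyte and microglial lists.

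Between 1 h and 6 h, 1964 probe sets of set A changed, 860 upward and 1104 downward, and 397 of set B changed, 164 upward and 233 downward. Median scaling of set A turned this balance, with 1114 upward and 689 downward, and moved the median of all probe sets from -0.05 to 0.05. The set B count was 97 on the deposited scale, 4 with median scaling and 12 with eBayes without trend. With the 6 arrays compared alone, 2095 probe sets changed on set A, and 263 on set B, 135 of them upward. On the brightest probe set of each gene, 604 named genes rose and 882 fell. Across the lists, 117 of 475 measured members changed (63 upward), 140 did on the probe set with the smallest p, and 142 did when adjusted over the list alone. With the summary method as a block, 812 probe sets of set B changed, and 859 with the replicate number as a block. Leaving out the 6 h replicates 1, 2 and 3 in turn gave 1257, 1030 and 1163 on set A; leaving out the 1 h replicates 1 and 3 and the 6 h replicates 2 and 3 gave 253, 173, 236 and 254 on set B.

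The 3 comparisons were combined to sort the probe sets of set A by time course. A transient course, up at 1 h and down again from 1 h to 6 h, held for 71 probe sets, of which 27 were still above 0 h at 6 h. A sustained course, past the threshold in the same direction at both times, held for 530 probe sets, 445 upward and 85 downward, and includes those 27. A late course, past the threshold at 6 h against both earlier times without passing at 1 h, held for 1377 probe sets, 545 upward and 832 downward. On set B the same counts were 2, 34 and 336, and they were 7, 94 and 675 with the replicate number as a block.

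Per gene, the transient class was taken first, so that sustained below leaves out transient genes still above 0 h. Among the immediate early genes 13 were transient. Btg2, Jun, Jund, Klf4 and Srf no longer passed against 0 h at 6 h, whereas Fos, Fosb, Junb, Egr1, Egr2, Egr4, Ier2 and Nr4a1 still did. A further 9 were sustained without passing as lower at 6 h than at 1 h, among them Npas4, Nfil3, Crem, Maff and Klf10, the last downward. Not passing here differs from no fall. Npas4 stood at -1.52 between 1 h and 6 h (limma adjusted p = 0.0864), with a lower signal at 6 h for each replicate number. Signalling effectors had 8 transient members, 5 of them still above 0 h at 6 h, and 4 sustained and 5 late ones. The secreted factors had no transient member, 4 sustained (Adcyap1, Pnoc, Scg2 and Vgf) and 6 late ones, namely Bdnf, Nptx2, Nrn1, Pcsk1, Plat and Tac1. Late here means not passing at 1 h, which differs from no change at 1 h. On their brightest probe sets Pcsk1 stood at 1.47 at 1 h (limma adjusted p = 0.0685) and Bdnf at 1.10 (limma adjusted p = 0.0785). The other probe set of Bdnf passed at 1 h (1.97), so the class of Bdnf depends on the probe set. Cholesterol synthesis genes had 5 late rises and 2 late falls, and glycolysis genes had 5 and 3. The excitatory synapse and voltage-gated channel lists each had 4 late falls.

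**Figure D4:**
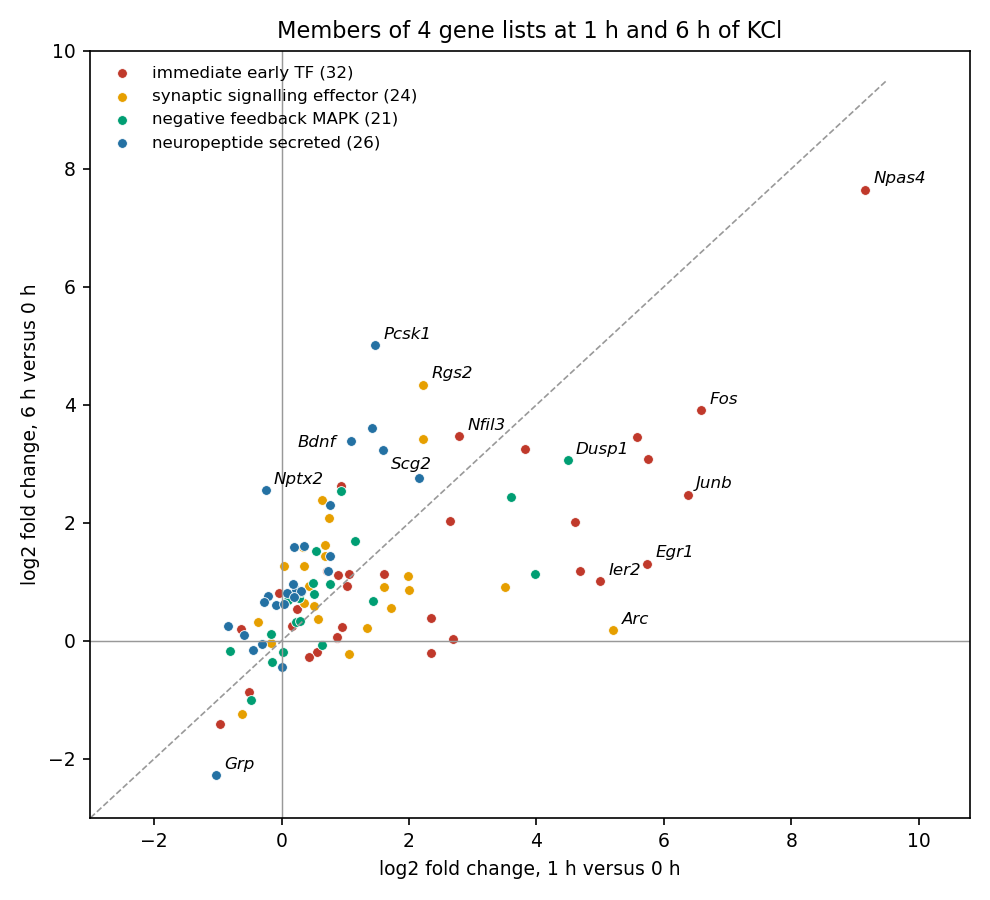
Log2 fold change at 6 h (vertical axis) against that at 1 h (horizontal axis), both versus 0 h, for the measured members of 4 gene lists; each point is a gene and the dashed line marks equal change. Arc lay at 5.21 and 0.18, Egr1 at 5.74 and 1.31, Fos at 6.58 and 3.91, Pcsk1 at 1.47 and 5.01, and Scg2 at 1.59 and 3.23.

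The 1 h and 6 h comparisons share their 0 h arrays. Across the probe sets of set A, which are not independent replicates, their fold changes had a correlation of 0.61, and simulated unchanged groups against the same controls gave 0.50. The covariance was 0.194 against 0.0441 in the simulation, a difference of 0.150. On set A 445 probe sets were higher at both times, where independent lists would share 57.6. For falls the numbers were 85 and 18.1. On set B the correlation was 0.505 against 0.501 simulated, and the covariance 0.298 against 0.265. On that set 28 probe sets were higher at both times against 0.668 for independent lists, and 6 were lower against 0.195. The 3 control arrays cannot be split further, so part of the excess may come from the shared controls. The simulated groups held no change, so they do not show how much shared controls add among changed probe sets.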

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

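The question about dim probe sets in the first pattern, the correlation by rank, the intervals and the choice of genes with opposite changes were set only after the results had been seen. The control probe sets had not been part of a planned comparison, and they were given a closer look because every array of a later time lay above every 0 h array of the same set. The ratio of 5' to 3' signal of Actb averaged 0.669 at 1 h and 0.574 at 6 h on set A (0.391 at 0 h), and 0.650 at 1 h and 0.574 at 6 h on set B (0.366 at 0 h). The same ratio of Gapdh averaged 1.21 at 6 h on set A (0.859 at 0 h) and 1.21 on set B (0.855 at 0 h). The 3' control probe set of 18S rRNA on set A averaged 411 units at 1 h and 311 at 0 h.

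The first pattern is that probe sets other than the brightest of their gene rose more often at 1 h (6.39% of 5584) than the brightest ones did (2.19%) on set A. A lower 5' signal in the 0 h material may take part in this. Within the time groups, the mean difference between the other and the brightest probe sets of 3649 genes went with the Gapdh 5' to 3' ratio of the array (Pearson r = 0.934, one-sided exact permutation p = 0.0324 over 216 permutations; Spearman rho = 0.767, one-sided permutation p = 0.0648; 9 arrays). Without the 0 h replicates 2 and 3 the correlation was 0.443 (one-sided exact permutation p = 0.194), so the relation rests on those arrays, and the 5' to 3' ratio remains open as the cause. Dimness of the other probe sets is excluded as the sole cause, since among the brightest 25% of probe sets the ratio of the shares was 3.90 (11.2% against 2.89%), and a biological source such as new or unspliced transcripts could not be tested with these data.

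The second pattern is that a smaller share of probe sets changed at 6 h on set B than on set A. With all arrays 22.1% changed on set A and 5.01% on set B. With replicates 2 and 3 alone, which hold no values below 0 on either set, 10.2% and 4.53% changed, a ratio of 2.25 (95% interval 2.06 to 2.45). The difference thus remained without the arrays that hold values below 0, so their mixture with the others on set B is not the whole cause, though it may be part of it. Whether sets A and B share a summary method is not known, so a method difference between the sets cannot be excluded. The intervals here treat probe sets as independent and do not cover variation between arrays. When set A probe sets were matched in signal to 10974 of the 16883 set B probe sets, those in 13 of 20 signal bins, the shares were 6.45% and 6.73%, a ratio of 0.959 (0.865 to 1.06). For this part of set B dimmer transcripts are consistent with the difference, and the part left out was not compared.

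The third pattern is that ribosomal protein and respiratory chain genes stood higher at 6 h than at 1 h on set A, with a median of 0.28 log2 over 53 genes. On the deposited scale this median lay at percentile 100 of 10000 random sets matched in signal (0.05 at the median, -0.04 to 0.17). Probe sets of like brightness thus shifted less at the median. Random sets were drawn gene by gene, while the estimated correlation was 0.311 within the ribosomal list and 0.324 within the respiratory chain list. Their range is therefore too narrow to exclude a shift with the array scaling. Without the 1 h replicate 1 array the median was 0.19, a share of 0.683 of the full value, so low values on that array may account for part of it and this explanation remains open. The adjusted p with an estimated correlation was 0.619 for ribosomal proteins and 0.782 for the respiratory chain. With quantile normalization it was 0.0525 and 0.154 by the preset test, so the calls depend on the scaling and no biological reading is drawn.

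In 3 genes, by their brightest probe set, both changes against 0 h passed with opposite signs. Adipor2 stood at -0.60 at 1 h (adjusted p = 0.0378) and 0.43 at 6 h (adjusted p = 0.0483), a difference of 1.03 log2. Hnrnpdl stood at 0.58 (adjusted p = 0.0117) and -0.36 (adjusted p = 0.0325), a difference of -0.93. Rhob stood at 0.42 (adjusted p = 0.0471) and -0.63 (adjusted p = 0.00131), a difference of -1.05. These differences follow from how the genes were chosen, and the number of such genes to expect by chance was not computed.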

How the results depend on the processing

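The fits with the summary method as a block, with replicates 2 and 3 alone, with the Gapdh 5' to 3' ratio as a covariate and with the brightest probe set of each gene were chosen only after the main results had been seen. No value of a named gene (up to 15 settings) or list (10 settings, not median scaling, array weights or eBayes without trend) past the threshold reversed its direction in the settings run for it or on leaving out 1 array, while the balance of rises and falls did turn in some. Where no cause is given below the cause was not tested. With 3 arrays per time the counts move widely, so each count is a description of 1 setting. A block for scan day or chip lot was not possible, since run files covered set B alone and named 1 lot and 1 day.

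On set A, 707 probe sets changed at 1 h, 3753 at 6 h and 1964 between 1 h and 6 h. Requiring at least 2-fold change gave 370, 1381 and 595, fewer by construction. At 1 h, eBayes without trend gave 265 and a fit of the 6 arrays compared gave 266. Replicates 2 and 3 alone, with fewer arrays, gave 90, 1728 and 552. The Gapdh 5' to 3' ratio as a covariate gave 64 at 1 h (61 of them among the 707) and 584 at 6 h (562 among the 3753). The ratio itself differs between the times, so this fit removes part of any change that goes with time. The brightest probe set of each gene alone gave 212 at 1 h and 2326 at 6 h, from 9981 tests in place of 16969. The smaller number of tests is not the only difference at 1 h. Among genes with several probe sets, 6.39% of the others rose against 2.19% of the brightest. The replicate block gave 1022, 4119 and 2332, and whether replicate numbers mark pairs on set A remains open. Only 2 of 9 same-number correlations were over 0.1 (0.0181 to 0.174), while in 9 of 9 comparisons between times the best match of an array was its own number. Median scaling gave 1114 upward and 689 downward between 1 h and 6 h, in place of 860 and 1104. At 6 h it gave 1851 and 1738 in place of 1772 and 1981.

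On set B, 37, 846 and 397 probe sets changed. Counts for 1 h, 6 h, and 6 h against 1 h were 116, 1468 and 859 with the replicate block, 111, 1428 and 812 with the summary method as a block, and 15, 443 and 97 on the deposited scale. Median scaling gave 5, 127 and 4, and eBayes without trend 5, 150 and 12. At 1 h, array weights gave 79, the 6 arrays compared 17, replicates 2 and 3 alone 20 and the covariate 4. At 6 h the covariate gave 122. Between 1 h and 6 h, at least 2-fold change gave 264 and the 6 arrays compared 263.

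Of 22 lists, 4 shifted at 1 h, 6 at 6 h and 5 between 1 h and 6 h. At 1 h, 7 shifted with the replicate block, 7 with a pseudocount of 64 and 10 with all probe sets of a gene. At 6 h, 2 shifted with an estimated correlation and 10 with the covariate. Between 1 h and 6 h, 0 shifted with an estimated correlation, 3 with quantile normalization (respiratory chain adjusted p = 0.154, ribosomal proteins 0.0525), and on set B, where 13 lists could be tested, 2 shifted and 1 of these was among the 5. With the replicate block the lists added at 1 h were ribosomal proteins, respiratory chain and astrocyte markers, all downward (adjusted p = 0.0300 each). The circadian list at 6 h no longer passed with that block (adjusted p = 0.0821), and it changed no other list call.

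The sustained and late classes held 530 and 1377 probe sets on set A, and 151 and 601 at an adjusted p under 0.01. On set B they held 34 and 336, and 15 and 119 at that threshold. The replicate block gave 7 transient, 94 sustained and 675 late probe sets on set B, and a pseudocount of 64 gave 5 transient ones in place of 2.

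Leaving out 1 array at a time moved the counts as follows. On set A they ran from 277 to 1308 at 1 h (293, 316 and 1308 without the 0 h replicates 1, 2 and 3, 353 and 277 without the 1 h replicates 1 and 3). They ran from 2606 to 3736 at 6 h, and from 1030 to 1768 between 1 h and 6 h (1257, 1030 and 1163 without the 6 h replicates 1, 2 and 3). On set B they ran from 9 to 70 at 1 h (24, 22 and 70 without the 0 h replicates 1, 2 and 3, 14 and 9 without the 1 h replicates 2 and 3). At 6 h they ran from 429 to 808 (551 and 429 without the 0 h replicates 1 and 2), and between 1 h and 6 h from 173 to 432 (253 and 173 without the 1 h replicates 1 and 3, 236 and 254 without the 6 h replicates 2 and 3). Shifted lists ran from 4 to 8 at 1 h (7, 7 and 8 without the 0 h replicates 1 and 3 and the 1 h replicate 2), from 5 to 8 at 6 h, and from 5 to 6 between 1 h and 6 h.

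Of 331 values of named genes, 199 passed the threshold, and 89 of these passed in every setting. Fos, Egr1, Junb, Nr4a1 and Arc at 1 h passed with the covariate, and none of the 10 largest falls at 1 h did (Txnip adjusted p = 0.227, Ppp1r3c 0.0696).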

Other observations

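The name groups and the pairs of neighbouring genes below were examined only after the results had been seen, and the groups were formed from shared gene-name stems of at least 10 genes on set A (111 stems). Tests were one-sided for an excess and adjusted over the stems within 1 comparison and direction, not over all comparisons and directions scanned. At 6 h against 0 h, genes of the Ube stem, which holds ubiquitin-conjugating enzymes and related ligases, rose more often than other genes. They were 10 of 29 against 8.05% (one-sided Fisher's exact test, adjusted p = 0.00635 over the stems). Ube2d3 (log2 1.11), Ube2w (1.07), Ube2h (0.74) and Ube2b (0.71) were among them, while Ube2d2a (-0.87) and Ube3b (-0.47) fell. In the Atp stem 13 of 57 rose against 8.04% (one-sided exact test, adjusted p = 0.0289). They included subunits of the vacuolar proton pump, Atp6ap2 (0.78), Atp6v0b (0.59), Atp6v1a (0.49), Atp6v1b2 (0.49), Atp6v1h (0.41) and Atp6v1c1 (0.37), as well as Atp8a1 (2.01) and Atp1b1 (0.73). The calcium pump gene Atp2b2 (-1.44) and Atp1b2 (-1.05) fell. The Rgs and Klf stems did not pass at 1 h (one-sided exact test, adjusted p = 0.0909 for each), and neither did the falls of the Zfp stem (5 of 139, adjusted p = 0.730). The test treats genes as independent, and genes of a stem can share regulation or probe sequence. Stems were not matched to the other genes in signal.

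By a one-sided test, genes that rose at 6 h and genes that fell at 6 h stood beside each other on the chromosome more often than in shuffles of the calls, the falls by a narrow margin. Of 15175 adjacent pairs among 15198 measured genes, both members rose in 75 (shuffled median 57, 44 to 72, one-sided permutation p = 0.0121, adjusted p = 0.0242 over 2 tests). Both fell in 190 (170, 147 to 193, one-sided permutation p = 0.0461, adjusted p = 0.0461), which lies inside the two-sided shuffled range. A name stem was shared in 5 and 4 of these pairs, and 70 and 186 did not share one. Overlapping transcripts and related neighbours remain possible explanations for the excess, so no biological reading is drawn. Gene order followed the GRCm38.p6 annotation.

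Exchanging arrays between the groups compared gives 10 splits, the real one included, which is too few for a share under 0.05. On set A the real counts were 707, 3753 and 1964 probe sets for 1 h, 6 h, and 6 h against 1 h, and the highest other split gave 1, 0 and 0. On set B the real counts were 37, 846 and 397 and no other split gave any. Of list members 58, 152 and 117 changed, with 0 in any other split; for all of these, 1 of 10 splits reached the real count. The numbers of shifted lists were 4, 6 and 5, and 5, 5 and 2 of 10 splits gave as many, with up to 7, 7 and 6 in another split, so the number of shifted lists by itself does not set the real grouping apart. Among 100 groupings of the 9 set A arrays into 3 groups, 1, the real one, reached the sum of 1978 over the time classes; the next highest gave 1178 with 7 arrays in their own group, and the one after it 23.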
